A study of Mus musculus with 3 samples.

How the data were processed

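RNA from the cytosolic fraction of lipid A stimulated mouse macrophages was sequenced after ribosomal RNA depletion in 3 libraries, labelled biological replicates 1 to 3 of a single group. Per the labels, the size range was 250 to 400, without a unit. The deposited text files that accompany each library name the assembly mm10 and the annotation GENCODE M21, with tRNA genes and spike-in sequences added for the alignment-based tables. The authors deposited, per library, a gene table and a transcript table from alignments to the transcriptome, and a transcript table made directly from the reads. Per the file headers, the first kind holds expected counts and TPM in the columns RSEM writes, and the second kind holds estimated counts and TPM in the columns kallisto writes. Expected counts and estimated counts in the deposited tables are not normalized and need not be whole. The deposited TPM values are scaled to a fixed sum over all targets of a table, so small abundant RNAs lower the TPM of every other gene. Tool versions and the strandedness of the counting are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. Lengths in the tables were used for the trend described below.

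From these values, gene levels were taken as the alignment-based gene TPM unless stated, and transcripts of the alignment-free tables were summed to genes. Of the alignment-based counts, 99.81, 99.83 and 99.96% lay on annotated genes, 0.1863, 0.1672 and 0.0395% on the phiX174 control sequence, 2, 4 and 1 counts on 26248 tRNA rows and 0 on 96 spike-in rows. Only gene rows entered library sizes and tests. Gene coordinates are those of mm10 and start at 1. The floors given for each library stand for 3 counts and cover counting error only, since reads without molecular identifiers are not independent molecules.

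Before the data were examined, 33 gene lists, every comparison and the rule for named genes were fixed; 5 listed names had no match in the annotation. The rule took, per list, the 4 members of highest mean TPM and up to 2 members below 1 TPM in all libraries, the 20 nuclear protein-coding genes of highest mean TPM, the 10 genes with the largest SD of log2 CPM at a mean count of 100 or more, the 5 genes per direction with the largest ratio between the quantifications, and a fixed set of macrophage and response genes. Not every gene the rule selects is printed.

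Lists were compared by the difference of their medians of log2(TPM + 0.1) within each library, with a two-sided permutation test of list membership on the mean over libraries (100000 permutations) and Benjamini-Hochberg adjustment within each family of comparisons. The pseudocount means that a fold change understates differences of genes near 0. For counts, expected counts were rounded to whole numbers, genes were filtered with filterByExpr and scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), and the common biological coefficient of variation was estimated with an intercept-only design. With a single group, no test between groups exists. The spread of a list and its shift in each library were medians over its genes of the SD of log2 CPM (prior count 2) and of the deviation from the gene's mean over the 3 libraries. Each was set against 10000 random lists of the same size matched on mean log2 CPM in 20 bins, for lists with at least 5 tested members, with a two-sided percentile p, which amounts to a permutation of list membership among genes of like abundance. Retained-intron shares were the percent of gene TPM on transcripts of that annotated type, and random lists were matched on abundance (10 bins) and number of transcripts (3 bins). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remainder.

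The steps were tested on simulated data. For the spread between replicates over 12744 genes, a coefficient of variation of 0.2 came back as 0.208, and 200 genes given a 2-fold change had a median log2 change of 1.01. For the list shift per library, a shift of 0.5 was recovered in 3 of 3 lists, and 0 of 60 tests on other lists were called. This simulation does not show how often a list is called when its genes vary together between libraries. For the comparison of early and late response genes, 9 of 200 pairs of random lists had p under 0.05.

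The alternatives tried were pseudocounts of 1 and 0.01, members of mean TPM of 1 or more, the alignment-free tables, list means, TPM over protein-coding and long noncoding genes, protein-coding transcripts alone, detection at 0.5 and 5 TPM, DESeq2 1.42.0 size factors or library size in place of TMM, other count minimums, edgeR tagwise dispersions, all transcripts that are not protein-coding, removal of a smooth trend on gene length and GC content (lowess fraction 0.3, 12737 genes with both values), and each replicate left out in turn. Chosen after seeing the data were scaled counts of the alignment-free tables for list spread, centred quantification ratios, leave-one-out list shifts, pairs over protein-coding genes, and the exported list without Rn7s1 and Rn7s2 or the nuclear list without Gm26917. Untreated cells, other times and other fractions were not analysed here.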

Results

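The libraries measured RNA from the cytosolic fraction of macrophages grown from mouse bone marrow (strain C57BL/6J). The cells had been stimulated for 25 minutes with 100 ng/ml lipid A, the lipid anchor of bacterial lipopolysaccharide and an agonist of the receptor TLR4. Ribosomal RNA was depleted, and each library started from 1 µg of RNA. All 3 libraries were biological replicates of a single group, so the comparisons were made between gene groups within each library and between the replicates, and no untreated level was measured here. Total expected counts were 53055764 in replicate 1, 43620362 in replicate 2 and 38623777 in replicate 3, and 3 counts corresponded to 0.0566, 0.0689 and 0.0777 CPM (counts scaled to the library total). At a level of 1 TPM (the deposited unit, scaled by transcript length and library) or more in every library, 9084 of 22015 protein-coding nuclear genes and 180 long noncoding RNA genes were detected. Of 627 distinct genes on 33 lists fixed before the data were examined, 429 were detected in this sense. Levels below are the mean TPM ± SD over the 3 libraries (n = 3).

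The first question was which classes of lipid A response genes were abundant in cytosolic RNA at 25 minutes. Immediate early genes, which encode transcription factors and feedback regulators, led with a median of 78.3 ± 30.7 TPM (SD, n = 3), and 26 of their 28 members were detected. Fos, a subunit of the factor AP-1 (mm10 chromosome 12, 85473890 to 85477273, plus strand), stood at 425 ± 101 TPM. Zfp36, whose protein binds and destabilises cytokine mRNAs (chromosome 7, 28376784 to 28380253, minus strand), stood at 399.7 ± 95.4 TPM, Junb at 260.0 ± 58.7 TPM and Ppp1r15a, a phosphatase subunit of the stress response, at 220.1 ± 135 TPM. Egr1 and Ier2 were at 212 ± 93.7 and 194 ± 62.6 TPM. Fosl1 was the single member below 1 TPM in every library, with 1, 2 and 0 counts.

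The list of fast NF-κB targets had a median of 22.5 ± 11.3 TPM and 31 of 32 members detected. Nfkbia, which encodes the inhibitor IκBα (chromosome 12, 55489410 to 55492647, minus strand), reached 259.7 ± 139 TPM, and the cytokine gene Tnf (chromosome 17, 35199381 to 35202007, minus strand) reached 208 ± 122.97 TPM. The chemokine genes Ccl3 and Ccl4, neighbours on chromosome 11, were at 185.5 ± 88.1 and 151.6 ± 51.2 TPM, and Cxcl2 was at 120.4 ± 58.8 TPM. Il1b, encoding interleukin 1β, was at 67.6 ± 45.8 TPM, Tnfaip3, encoding the NF-κB inhibitor A20, at 51.3 ± 25.1 TPM and Ptgs2, encoding cyclooxygenase 2, at 11.9 ± 4.84 TPM. Cxcl3 was the only listed target below 1 TPM in all libraries (8, 9 and 3 counts).

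Late response genes had a median of 0.46 ± 0.14 TPM. Of 25 members, 10 were detected and 14 were below 1 TPM in every library. Il6 was at 0.20 ± 0.11 TPM, Il12b, encoding a subunit of interleukin 12, at 0.27 ± 0.03 TPM, Il12a at 0.01 ± 0.01 TPM and Nos2, the inducible nitric oxide synthase, at 0.01 ± 0.01 TPM. The exceptions on this list included the monocyte chemoattractant genes Ccl2 at 52.7 ± 25.5 TPM and Ccl7 at 45.8 ± 19.0 TPM, the anti-inflammatory cytokine gene Il10 at 22.1 ± 13.4 TPM and Ccl5 at 13.4 ± 2.15 TPM. Interferon response genes had a median of 15.9 ± 8.57 TPM with 27 of 30 detected. Ifit2, Irf1 and Ifit3 were at 71.7 ± 36.4, 68.0 ± 45.5 and 65.5 ± 27.2 TPM, and Cxcl10 was at 21.99 ± 21.3 TPM. Ifnb1, the gene of interferon β itself, had 2, 2 and 3 counts, and Cxcl9 was at 0.06 ± 0.06 TPM.

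Immediate early genes lay above late genes by a log2 difference of medians of 7.09 ± 0.21 on log2(TPM + 0.1), a 136.5-fold difference, in 3 of 3 libraries (n = 3; two-sided permutation test over genes, p = 1e-05, the smallest the permutations can give; adjusted p = 2e-05 over 4 comparisons). Fast NF-κB targets lay above late genes by 5.26 ± 0.42 (permutation p = 1e-05; adjusted p = 2e-05), and immediate early genes lay above interferon response genes by 2.35 ± 0.41 (permutation p = 0.00219; adjusted p = 0.00292). Fast NF-κB targets and interferon response genes differed by 0.52 ± 0.15 in their medians, which the permutation test over genes did not separate (p = 0.412). With only members of mean TPM of 1 or more, the NF-κB to late difference was 1.61 and no longer passed the test (adjusted p = 0.0725). These p-values are over genes, which are not independent, so they describe these libraries, and the labels tie all 3 replicates to a single donor record without saying that they came from separate animals.

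**Figure D1:**
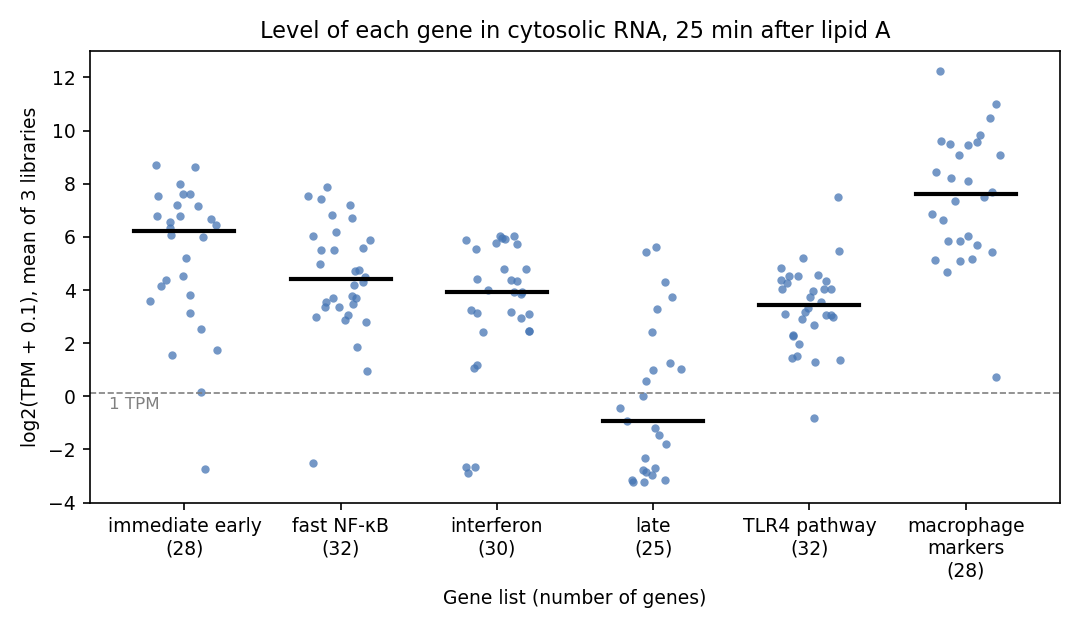
Each point is a gene, at its log2(TPM + 0.1) averaged over the 3 libraries, and black bars mark list medians; list sizes are in parentheses and the dashed line marks 1 TPM. Of the 4 response lists, the immediate early list lies highest and the late list lowest, with per-library medians that average 6.22 and -0.87.

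**Figure D2:**
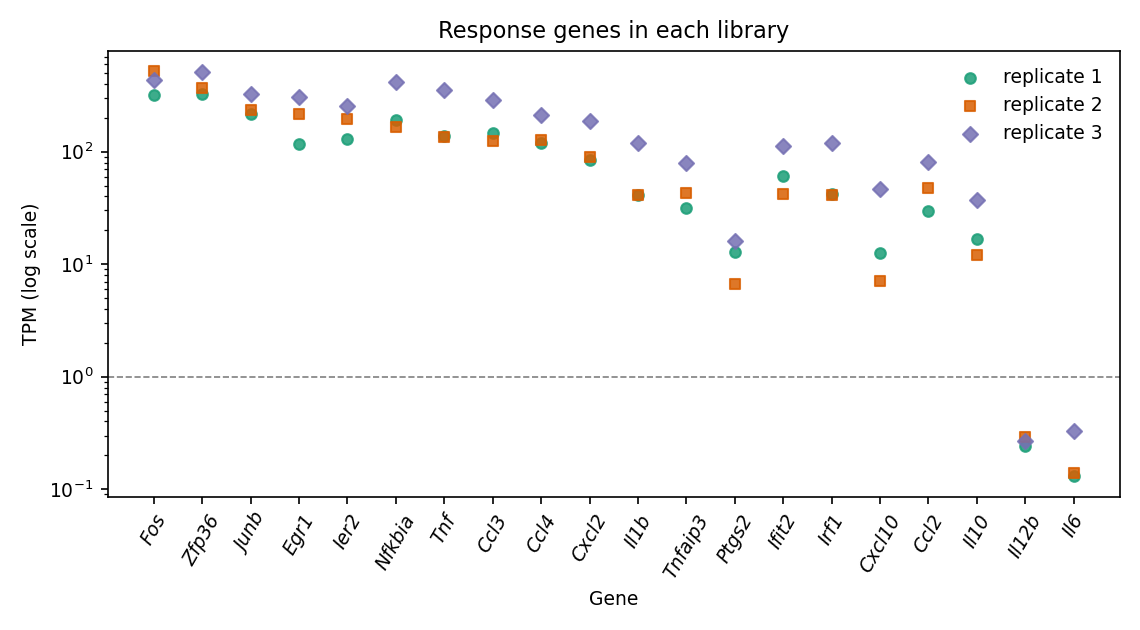
TPM of 20 response genes in each library, on a log axis, with replicate 1 as circles, replicate 2 as squares and replicate 3 as diamonds; the dashed line marks 1 TPM. Tnf stood at 138, 136 and 350 TPM in replicates 1 to 3, and Il6 and Il12b lay below 1 TPM in all of them. The larger TPM share of protein-coding genes raises TPM in replicate 3. In log2 CPM, Tnf was at 8.61, 8.49 and 9.54.

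Macrophage markers were the most abundant of the cell type lists, with all 28 members detected and a median of 190 ± 29.1 TPM. Lyz2, encoding lysozyme (chromosome 10, 117277331 to 117282321, minus strand), was at 4945 ± 1494 TPM, the apolipoprotein gene Apoe at 2062 ± 350 TPM, Lgals3 at 1413 ± 53.3 TPM, the cathepsin gene Ctss at 929 ± 163 TPM and Csf1r, the receptor of the growth factor M-CSF, at 299 ± 58.2 TPM. The iron storage genes Ftl1 (8365 ± 695 TPM) and Fth1 (7835 ± 859 TPM) were the highest nuclear protein-coding genes, followed by the lysosomal genes Psap (5085 ± 269 TPM), Ctsd (4121 ± 433 TPM) and Ctsb (2763 ± 625 TPM), together with Lyz2. Selenop, Gpnmb, Actb, Tmsb4x and Eef1a1 were also among the 20 highest, which held 14.0% of all counts.

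Erythroid, mast cell and stromal lists had 0 detected members of 13, 11 and 12, with no counts for the adult β-globin genes Hbb-bs and Hbb-bt in any library and Kit at 0.58 ± 0.20 TPM and Col1a1 at 0.03 ± 0.03 TPM. B-lineage, T and NK cell and megakaryocyte lists had 1 detected member each, namely Cd22 at 2.50 ± 0.67 TPM, Cd28 at 91.02 ± 14.3 TPM and the integrin gene Itgb3 at 4.94 ± 0.74 TPM. Cd28, known as a T cell costimulatory receptor (chromosome 1, 60716800 to 60773359, plus strand), stood apart from Cd3e and Cd3d, subunits of the T cell receptor complex, which had at most 3 counts in a library. Among neutrophil markers 4 of 15 were detected, S100a9 at 20.2 ± 6.22 TPM, S100a8 at 12.3 ± 2.67 TPM, Mmp8 at 5.25 ± 1.39 TPM and Ngp at 3.67 ± 2.22 TPM. Dendritic cell markers had 4 of 14 detected, led by Bst2 at 123.4 ± 38.4 TPM and Irf8 at 58.4 ± 9.06 TPM, endothelial markers 3 of 10, led by Vwf at 12.8 ± 1.49 TPM, and osteoclast markers 2 of 9, the proton pump gene Atp6v0d2 at 61.2 ± 14.6 TPM and Nfatc1 at 12.9 ± 3.40 TPM.

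The macrophage list exceeded the other 10 cell type lists by log2 differences of medians between 8.36 ± 0.64 (dendritic) and 10.88 ± 0.22 (erythroid), in 3 of 3 libraries each. The neutrophil list lay 9.17 ± 0.87 below it, the osteoclast list 8.81 ± 0.46, the T and NK list 10.84 ± 0.29, the B-lineage list 10.61 ± 0.37, the mast cell list 10.38 ± 0.66, the megakaryocyte list 9.91 ± 0.63, the stromal list 10.79 ± 0.29 and the endothelial list 10.04 ± 0.03. Every adjusted p was at or below 2e-05 (permutation test over genes, n = 3 libraries). For macrophage cultures this direction was likely from the choice of the lists, so these p-values do not measure purity. The erythroid, T and NK and stromal medians of log2(TPM + 0.1) were -3.32, -3.28 and -3.23. These lie near the lowest value the pseudocount allows, which sets the size of those differences. With only members of mean TPM of 1 or more, the differences from the T and NK, B-lineage and megakaryocyte lists were 1.06, 6.22 and 5.24 and did not pass the test (adjusted p = 0.727, 0.0806 and 0.0806). A single member remained on each of these lists, Cd28, Cd22 and Itgb3.

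Components of the TLR4 pathway were present, with 31 of 32 members detected. Cd14, the co-receptor that hands lipopolysaccharide to TLR4, was at 185 ± 29.3 TPM, Tlr4 itself (chromosome 4, 66827584 to 66930284, plus strand) at 28.5 ± 5.65 TPM and Ly96, encoding the lipid A binding protein MD-2, at 15.96 ± 4.61 TPM, while Lbp, a serum protein gene, was at 0.49 ± 0.23 TPM. Pattern recognition receptors had 21 of 26 detected, led by the scavenger receptor gene Cd36 at 136.3 ± 69.4 TPM, and Tlr11 and Tlr12 were at 0.05 ± 0.02 and 0.03 ± 0.01 TPM. Of the interleukin and TNF family genes 12 of 32 were detected, with Tgfb1 at 147 ± 12.1 TPM beside Tnf, and of the chemokines 14 of 26, with Pf4 at 184 ± 33.2 TPM and Ccl6 at 150 ± 30.7 TPM beside Ccl3 and Ccl4. Among NF-κB, IRF, STAT and AP-1 factors 32 of 34 were detected, Jun at 113.5 ± 39.9 TPM, with Irf4 and Stat4 at 0.61 ± 0.09 and 0.54 ± 0.22 TPM. Genes of alternative activation were split, with 8 of 14 detected, Mrc1, the mannose receptor gene, at 117.2 ± 12.3 TPM and Arg1 and Retnla at 0.04 ± 0.05 and 0.01 ± 0.02 TPM.

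Housekeeping groups were almost fully detected. All 26 lysosomal genes had a median of 210 ± 25.9 TPM, all 38 ribosomal protein genes 240 ± 61.4 TPM (Rplp1 733 ± 165), all 19 glycolysis genes 58.6 ± 3.54 TPM (Gapdh 311 ± 45.9) and all 28 nuclear genes of oxidative phosphorylation 44.3 ± 9.91 TPM (Cox4i1 222 ± 42.3). Of the mitochondrially encoded genes 12 of 13 were detected, and mt-Co1, a subunit of cytochrome c oxidase, was at 1015 ± 216 TPM. The exception, mt-Co2, was at 0.1, 12.8 and 25.9 TPM, a level made uncertain by copies of mitochondrial sequence on chromosome 1. Counts of mt-Atp6, mt-Co3 and mt-Nd4l also differed between the quantifications, as given below, so their levels are uncertain too. Antigen presentation had 16 of 18 detected, with B2m at 1691 ± 598 TPM and Ciita, the activator of class II genes, at 0.74 ± 0.17 TPM. Heat shock and endoplasmic reticulum stress genes had 17 of 21 detected, led by Hspa8 at 413 ± 87.0 TPM, with the inducible Hspa1b at 0.70 ± 0.22 TPM. Cell-cycle genes had 15 of 30 detected at a median of 1.66 ± 0.72 TPM, with Pcna at 64.9 ± 4.73 TPM and the cyclin E genes Ccne1 and Ccne2 at 0.62 ± 0.18 and 0.56 ± 0.19 TPM. Replication histone genes had 24 of 28 detected at a median of 7.53 ± 2.78 TPM.

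Small structured RNAs took most of the TPM in the alignment-based tables, though not in the alignment-free ones, where 7SL held 15.1 ± 6.60% of TPM and 7SK 2.10 ± 1.35%. The 7SL RNA of the signal recognition particle, which targets secretory proteins to the endoplasmic reticulum, held in the former 58.6 ± 1.06% of TPM and 10.2 ± 0.55% of counts (n = 3), assigned to Rn7s1 and Rn7s2 on chromosome 12, near-identical copies whose reads cannot be divided with confidence. The 7SK RNA gene Rn7sk held 7.51 ± 1.89% of TPM, RNase P RNA, encoded by Rpph1, 4.14 ± 0.97% and RNase MRP RNA 2.10 ± 0.61%. In all, 8 of 11 small structured RNAs were detected, and the Y RNA genes Rny1 and Rny3 had 0 counts in each library. Both genes are short (chromosome 6, 47788069 to 47788180 and 47781624 to 47781725). Whether RNAs of that length could be counted was not tested, so 0 counts do not show absence. Protein-coding nuclear genes held 84.8 ± 1.70% of counts but 25.1 ± 4.04% of TPM. Their TPM share was 22.7, 22.9 and 29.8% in replicates 1 to 3, so TPM of these genes are raised in replicate 3 relative to the other libraries by this share alone.

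**Figure D3:**
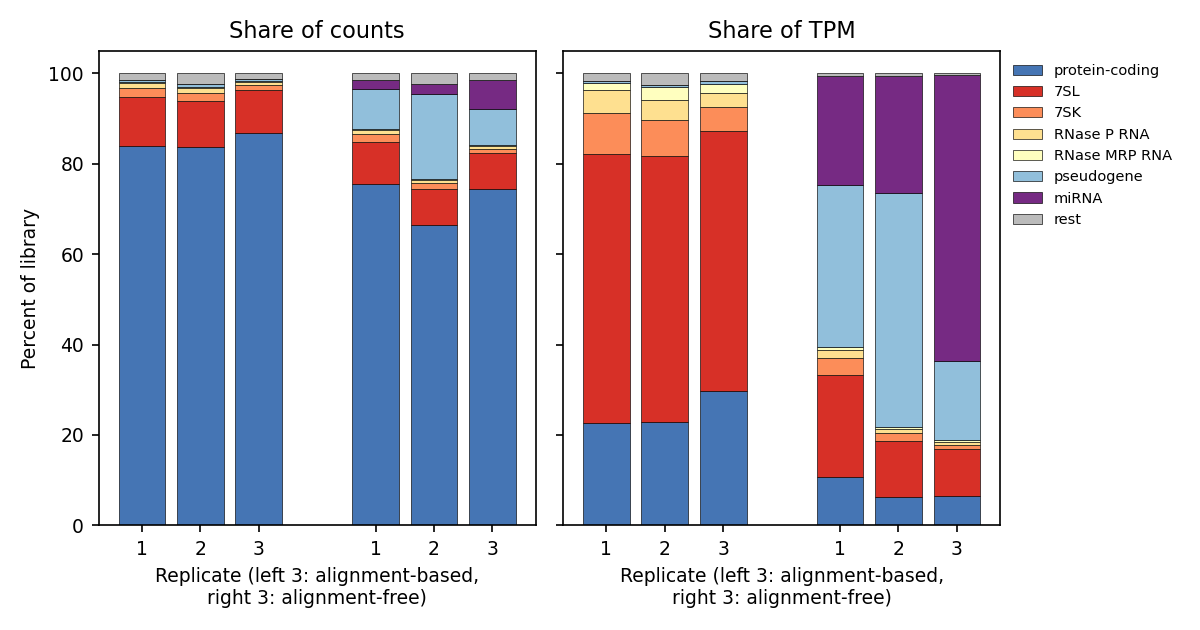
Stacked bars give the percent of counts (left panel) and of TPM (right panel) by RNA class in each library, for the alignment-based quantification (left 3 bars) and the alignment-free quantification (right 3 bars). 7SL RNA took 57.4 to 59.5% of TPM in the former, and pseudogenes and miRNA genes together took most of the TPM in the latter.

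The labels name a cytosolic fraction, and noncoding RNAs listed beforehand as exported were compared with RNAs listed as staying in the nucleus. Where members such as Tug1 reside in these cells was not tested. Of 13 exported RNAs 11 were detected, among them Gas5 at 33.5 ± 8.11 TPM and Tug1 at 18.5 ± 3.66 TPM, whereas 8 of 13 nuclear RNAs were below 1 TPM in every library, with 0 counts for Meg3. Malat1, a nuclear speckle RNA (chromosome 19, 5795690 to 5802672, minus strand), was at 392, 1144 and 374 TPM in replicates 1 to 3, and Neat1, the scaffold of paraspeckles and close to Malat1 on chromosome 19, was at 32.4, 106.5 and 37.3 TPM. Gm26917 was at 36.6, 240.7 and 54.2 TPM, and Xist, which coats the inactive X chromosome, at 1.63, 11.9 and 3.70 TPM. Gm26917 ends just before CT010467.1, a gene annotated as ribosomal RNA, so its place on the nuclear list is uncertain. The median log2 difference, exported minus nuclear, was 4.52 ± 0.48 in 3 of 3 libraries (n = 3, two-sided permutation test over genes, p = 0.0196). It turned to -2.57 (permutation p = 0.111) with only members of mean TPM of 1 or more, and without Rn7s1 and Rn7s2, an alternative added after the data were seen, it was 4.07 (adjusted p = 0.05). No nuclear or total RNA was analysed here, so a nuclear RNA at a low level may simply not be expressed in these cells. The comparison therefore cannot show how pure the fraction was.

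Pairs of replicates were compared gene by gene. Among 10345 genes with a mean count of 100 or more, 138 were over 2-fold higher and 14 over 2-fold lower in replicate 2 than in replicate 1, 35 were higher and 18 lower in replicate 3 than in replicate 1, and 84 were higher and 208 lower in replicate 3 than in replicate 2. A check for a library deposited more than once, which covers counting error only and says nothing on the size of biological variation, gave a chi-square per degree of freedom of 59.9, 51.2 and 91.3 for these pairs, and no pair was treated as a copy. Restricting the count to protein-coding genes, chosen after the data were seen, left 83 genes higher in replicate 2 than in replicate 1 and 9 lower in replicate 3 than in replicate 1. Over all genes, lowering the minimum to a mean count of 20 gave 472 and 64 in place of 138 and 18. The common biological coefficient of variation from edgeR was 15.2% over 12744 genes, and it was 10.03% without replicate 2.

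The genes that varied most between libraries were mainly genes whose reads overlap or duplicate others. CT010467.1, annotated as ribosomal RNA (chromosome 17, 39846353 to 39848827, minus strand), had 1715, 4485 and 26382 counts in replicates 1 to 3, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 had 247 and 196 counts in replicate 1 and 1828 and 1791 in replicate 3. Gm49369, which overlaps Ctsd on the same strand, was at 728, 1210 and 95.2 TPM. Gm42742 overlaps Pagr1a, Gm15725 lies within Lrrc58, and Gm17122 and Rps12l1 lie opposite Coro1c and Nipa1, so their counts are uncertain. Of the remaining members of the 10 most variable genes, Gm14296 had 76, 413 and 43 counts and Nptx1, encoding a neuronal pentraxin, 56, 301 and 31.

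Response genes varied more between the replicates than other genes of like abundance. The median SD of log2 CPM was 0.403 for fast NF-κB targets against 0.093 for matched random lists, a ratio of 4.34, and the ratio was 4.07 for interferon response genes, 3.14 for immediate early genes and 2.29 for late genes. It was 7.71 for nuclear-retained RNAs, 5.39 for mitochondrially encoded genes and 3.83 for cell-cycle genes. Against them, TLR4 pathway genes had a ratio of 1.11 and lysosomal genes 0.95, neither past the test (adjusted p = 0.505 and 0.764). Of 28 lists tested, 18 varied more than matched lists and 0 less at an adjusted p under 0.05 (permutation of list membership over 10000 random lists, where p = 0.0002 is the smallest they can give). These p-values are over genes, not replicates, and lists of genes that vary together pass more easily. Single libraries decided some of these ratios. Without replicate 2 they were 1.01 for nuclear-retained RNAs, 1.13 for cell-cycle genes and 5.94 for immediate early genes (1.83 without replicate 1), and without replicate 3 they were 1.16 for mitochondrially encoded genes, 1.62 for fast NF-κB targets and 1.64 for late genes, the last no longer past the test, as also without replicate 1 (1.93). The ratios of 1.01, 1.13 and 1.16 were close to that of the TLR4 pathway over all libraries (1.11), which did not pass. On TPM of the alignment-free quantification, which were not rescaled between libraries, 8 lists were above and 6 below their matched lists, with fast NF-κB targets at 0.75, whereas scaled counts of that quantification, tried after the data were seen, gave 16 above and 0 below.

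Replicate 3 held more of the response transcripts. Of 31 fast NF-κB targets tested, 28 were highest in replicate 3, by a median of 1.54-fold over the other libraries, and the list lay 0.42 above the mean of the 3 libraries on the log2 CPM scale. Nfkbia was at 9.02, 8.7 and 9.74 log2 CPM in replicates 1 to 3, and Il1b at 6.44, 6.26 and 7.63. Interferon response genes lay 0.31 higher in replicate 3 (25 of 27 members highest there), immediate early genes 0.22 (19 of 27) and late genes 0.30 (10 of 16). Cxcl10 was at 4.47, 3.6 and 5.96 log2 CPM in replicates 1 to 3. Interleukin and TNF family genes (0.42, 15 of 18) and chemokines (0.35, 13 of 18), which share members with those lists, lay higher there too, as did antigen presentation (0.19), pattern receptors (0.15), NF-κB, IRF, STAT and AP-1 factors (0.11), ribosomal proteins (0.11) and the TLR4 pathway (0.08). In the same library mitochondrially encoded genes lay at -0.57, neutrophil markers at -0.62, replication histones at -0.53, small structured RNAs at -0.38 and glycolysis genes at -0.06. Nuclear-retained RNAs (-0.54) and cell-cycle genes (-0.28) lay lower there as well, but without replicate 2 these shifts were -0.01 and 0.01 and did not pass. Other shifts still passed with a library left out but were smaller in size. Part of each fall is by construction, since the named library weighs more in a mean of 2 libraries than in a mean of 3. Without replicate 2, interferon response genes lay 0.15, the NF-κB, IRF, STAT and AP-1 factors 0.05 and the TLR4 pathway 0.04 higher in replicate 3, with neutrophil markers at -0.24, replication histones at -0.23 and small structured RNAs at -0.12. Without replicate 1, immediate early genes lay 0.10, late genes 0.16, chemokines 0.19, antigen presentation 0.11 and pattern receptors 0.09 higher.

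Nuclear-retained RNAs and cell-cycle genes were higher in replicate 2. All 8 nuclear-retained RNAs tested were highest there, by a median of 3.53-fold, and the list lay 1.21 above the mean of the 3 libraries. All 30 cell-cycle genes were highest in replicate 2, by a median of 1.87-fold (list shift 0.60), as were 25 of 28 replication histone genes (0.54), 7 of 8 neutrophil markers (0.55), 7 of 11 dendritic cell markers (0.41) and 9 of 12 mitochondrially encoded genes (0.32). The 3 most abundant dendritic cell markers were lowest there instead, so that rise rests on members of lower level. In log2 CPM for replicates 1 to 3, Bst2 was at 7.06, 6.58 and 7.18, Irf8 at 8.07, 8.04 and 8.06 and Tcf4 at 7.04, 6.92 and 7.1. Ccnd1, encoding cyclin D1, had 3038, 4154 and 1497 counts in replicates 1 to 3. Ribosomal protein genes were lowest in replicate 2 in 38 of 38 cases (-0.19), and interferon response genes (-0.37, 24 of 27 lowest), interleukin and TNF family genes (-0.37), fast NF-κB targets (-0.16) and nuclear genes of oxidative phosphorylation (-0.11) also lay lower. Without replicate 3 the shifts were -0.08 for interleukin and TNF family genes, -0.19 for interferon response genes, -0.06 for oxidative phosphorylation, 0.31 for replication histones and 0.34 for neutrophil markers, and without replicate 1 that of dendritic cell markers was 0.25, all still past the test. Part of each fall is again by construction. Abundant small RNAs known as nuclear went both ways. Rn7sk and Rpph1 were highest in replicate 1, at 14.40, 14.14 and 13.44 and at 13.39, 13.14 and 12.50 log2 CPM in replicates 1 to 3, whereas Rmrp, the RNA of RNase MRP, was highest in replicate 2, at 10.73, 11.36 and 10.48.

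Each of these shifts passed the comparison with matched random lists (adjusted p at or below 0.0449, with 43 of 84 list and library pairs passing). These p-values are over genes, which can vary together and are not replicates, so they describe these libraries only. The smallest p the random lists can give, 0.0002 (adjusted p = 0.000525), was reached by the replicate 3 shifts of the fast NF-κB, interferon, immediate early and late lists and by the replicate 2 shifts of the nuclear-retained, cell-cycle, histone and ribosomal protein lists. When the other libraries were set against the named one in turn, also chosen after the data were seen, fast NF-κB targets lay 0.28 to 0.30 higher in replicate 3, and nuclear-retained RNAs 0.85 to 0.88 and cell-cycle genes 0.43 to 0.45 higher in replicate 2. Being deviations from a mean of 2 libraries, these values are by construction smaller than the shifts over 3. The replicate 3 shift of ribosomal proteins without replicate 2 (0.02) and the replicate 2 shifts of fast NF-κB targets (-0.00) and mitochondrially encoded genes (0.03) without replicate 3 did not pass. With alignment-free counts the calls ended for dendritic markers (adjusted p = 0.165), small structured RNAs (adjusted p = 0.0664) and glycolysis (adjusted p = 0.0622), and with a trend on length and GC content removed that of oxidative phosphorylation in replicate 2 did (-0.02).

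**Figure D4:**
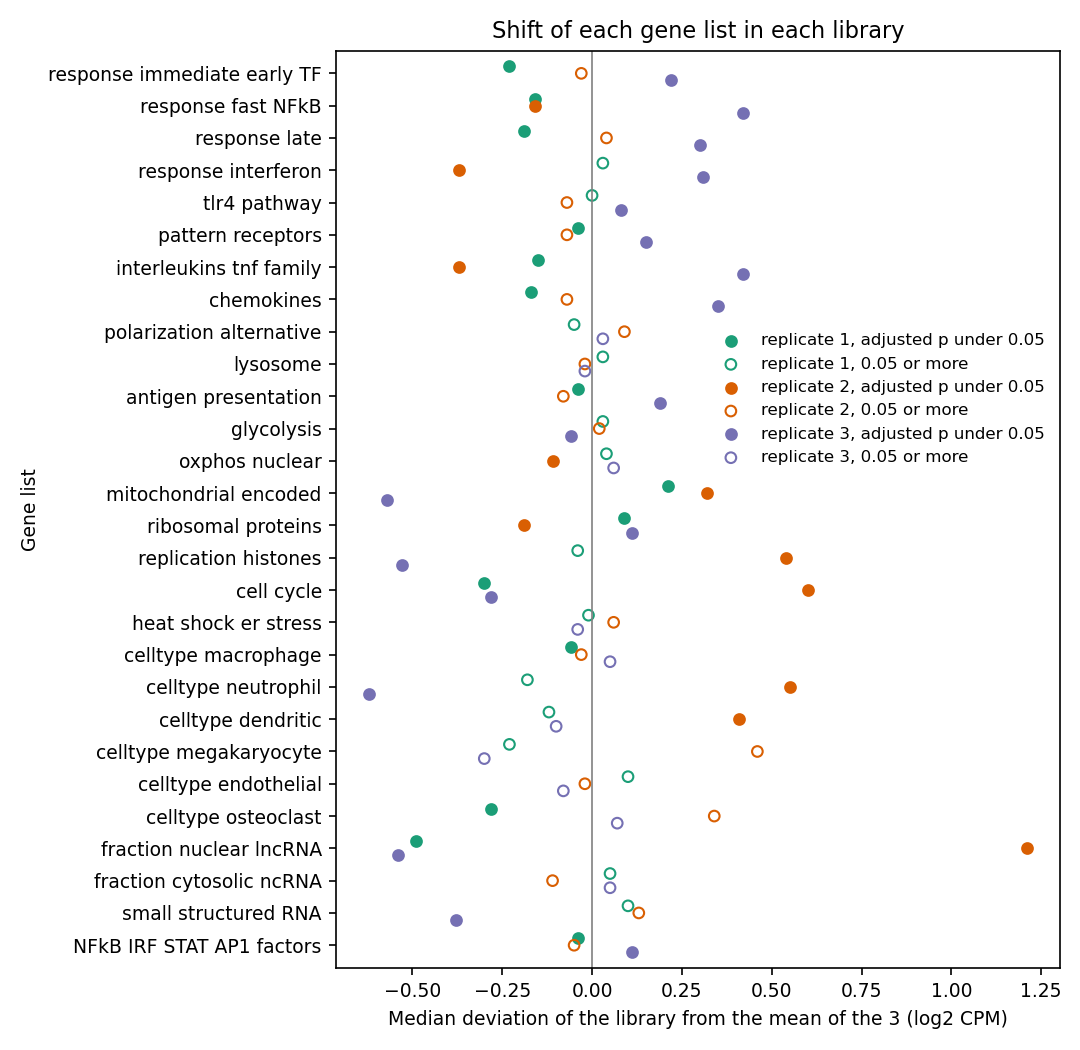
Each point is the median deviation of a list's genes in a library from their mean over the 3 libraries, in log2 CPM, for 28 gene lists; filled points passed the comparison with matched random lists at an adjusted p under 0.05, open points did not. Replicate 3 lies highest for fast NF-κB targets (0.42) and replicate 2 for nuclear-retained RNAs (1.21) and cell-cycle genes (0.60).

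Some response mRNAs carried reads assigned to transcripts annotated as retaining an intron. For fast NF-κB targets the median share of gene TPM on such transcripts was 3.14%, against 0.07% in lists matched on abundance and number of transcripts, and for chemokines 2.28% against 0.00% (permutation of list membership, p = 0.0002, the smallest the random lists can give; adjusted p = 0.0019 for both). The share was 17.9 ± 8.1% for Tnfaip3, 16.9 ± 10.2% for Cxcl2, 12.8 ± 7.4% for Il1b and 18.0 ± 9.1% for Ccl6 (SD, n = 3), while Tnf, Ccl3 and Ptgs2 had 0.0%. Cd83, a maturation marker named after its value was seen, had the highest share among the NF-κB targets at 73.7 ± 1.7%. None of the other 17 lists tested passed, including immediate early genes (median 0.0%) and interferon response genes (0.94% against 0.25%, adjusted p = 0.628). Without replicate 2 the NF-κB share was 1.89% and still passed. A gene with no annotated transcript of this type scores 0.0%, so such a value does not show complete splicing. The random lists were not matched on having such a transcript, so annotation may account for part of these differences.

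Retained-intron shares were also compared between the libraries. Of 5488 protein-coding genes with any such signal, 71.8% had their highest share in replicate 2, against 13.0% in replicate 1 and 15.2% in replicate 3, and the mean share over 9083 genes was 3.83, 5.18 and 3.72% in replicates 1 to 3. Tnfaip3 followed this with 17.1, 26.4 and 10.3%, and Cxcl2 with 13.9, 28.3 and 8.5%.

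Each library had been quantified in an alignment-based and an alignment-free way, and the results differed most for short RNAs and gene copies. The processed pseudogenes Gm12896 and Gm12895 on chromosome 4, each 226 nt long, had 0 counts in the alignment-based tables but 178372, 257171 and 87469 TPM (Gm12896) in the alignment-free tables. The 57-nt miRNA genes Gm23935, Gm24270 and Gm24245 had 0 counts in the former and shared identical values of 79757, 86505 and 210297 TPM in the latter. In the other direction, Gm10222 and Gm10925, copies of mitochondrial sequence on chromosome 1, were at 299 ± 43.8 and 566 ± 160 TPM in the alignment-based tables and at most 1.6 TPM in the alignment-free ones. Gm10443, a pseudogene, Gm10076 and Gm26716, which lies opposite Sdc3, were likewise at most at 0.6 TPM in the alignment-free tables. For mt-Co2 the quantifications differed as well, with 5, 484 and 738 alignment-based counts and 4337, 3556 and 3972 alignment-free counts. In the same stretch of chromosome 1, Gm28661 held far more, with 49251, 41623 and 22213 alignment-based and 47549, 41138 and 20507 alignment-free counts. For mt-Atp6 the counts were 3419, 2477 and 5853 against 36583, 29470 and 18232, so the order of the libraries changed. Alignment-free counts were also higher for mt-Co3 and mt-Nd4l. How each method divided reads between mitochondrial genes and such copies was not tested, so the levels of these 4 genes are uncertain. The spread and shifts given above for mitochondrially encoded genes rest on alignment-based counts that include such genes.

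Among 3990 genes at a mean of 10 TPM or more in either quantification, 34 were over 2-fold higher and 2983 over 2-fold lower by the alignment-free method in all 3 libraries. The median log2 ratio over these genes was -1.10, -1.86 and -2.17 in replicates 1 to 3, and 2873 of the lower genes were protein-coding. Protein-coding genes as a class held 22.67, 22.86 and 29.76% of alignment-based TPM in replicates 1 to 3. They held 10.66, 6.27 and 6.54% of alignment-free TPM, where pseudogenes and miRNA genes took most. Since TPM have a fixed sum, this smaller share lowers nearly all these genes together, so the 2983 are mostly not disagreements gene by gene. With ratios centred on that median, a choice made after the data were seen, 55 genes were higher and 62 lower, although such centring by construction puts as many ratios above the median as below it. Over genes longer than 200 nt with rescaled TPM, 23 were higher and 142 lower.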

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

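The tests of a later effective time and of granulocyte-lineage cells below were chosen only after the results they bear on had been seen. The design holds a single group and so names no biological difference to set against the explanations tested.

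Reads of the phiX174 control genome, which no comparison uses, made up 0.1863% of alignment-based counts in replicate 1, 0.1672% in replicate 2 and 0.0395% in replicate 3, listed here because this sequence lies outside the main measurement. Any share above the limit that a count of 0 allows is listed, so this says only that such reads were present.

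Fast NF-κB response genes were higher in replicate 3, with 28 of 31 members highest there. A bias by GC content or gene length is argued against, because the list shift stayed at 0.42 log2 once a trend on both was removed, while that removal moved single deviations by a median of 0.019. A later effective time after stimulation might raise these genes more than the immediate early genes, and their shift was larger by 0.20 log2, but the permutation test over genes gave p = 0.0953. With 3 libraries and a single time, a later effective time and another difference between the cultures cannot be told apart.

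Nuclear-retained RNAs were higher in replicate 2, with 8 of 8 members highest there. GC content or length is argued against, since removing that trend left a shift of 1.15. Nuclear RNA carried into the cytosolic fraction is a candidate explanation that the data could have contradicted: incompletely spliced transcripts should then be enriched in the same library. Of protein-coding genes with a retained-intron signal, 71.8% had their highest share in replicate 2, where an even split gives 33.3% (79.6% of 4278 genes in the alignment-free tables). These genes share the same 3 libraries and are not independent, so any difference that affects all of replicate 2 could also move this share. Other RNAs known as nuclear went both ways, with Rn7sk (14.40, 14.14 and 13.44 log2 CPM in replicates 1 to 3) and Rpph1 (13.39, 13.14 and 12.50) highest in replicate 1 and Rmrp (10.73, 11.36 and 10.48) highest in replicate 2. These RNAs are short, and how length bore on their counts in each library was not tested. Their order therefore decides nothing on nuclear carry-over. Small nuclear RNAs were at 0.67, 1.16 and 0.74% of alignment-based TPM and at 0.13, 0.12 and 0.08% of alignment-free TPM. The latter are not scaled between libraries, and protein-coding genes held 10.66, 6.27 and 6.54% of them, so that order is uncertain. Of alignment-free counts, small nuclear RNAs made up 0.02, 0.03 and 0.02%, and of alignment-based counts 0.02% in each library.

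Cell-cycle genes were higher in replicate 2, with 30 of 30 members highest there. GC content or length is argued against, since removing that trend left their shift at 0.60. Carried-over nuclear RNA stays open: they lay 0.59 above lists matched on abundance and on the change in retained-intron share, but medians of 5 groups of genes ordered by that change ran only from -0.027 to 0.029, so matching on it could remove little of the shift and decides nothing. Cells of the granulocyte lineage and their progenitors might add such transcripts, and neutrophil markers also lay 0.55 higher in replicate 2, with S100a9 at 15.9, 27.4 and 17.4 TPM and S100a8 at 9.60, 14.9 and 12.4 TPM in replicates 1 to 3. The neutrophil list gained 19.6 summed TPM in replicate 2 against 47.2 for the cell-cycle list, a ratio of 0.42, and at 4 of 15 markers detected and no sort named in the labels, such cells, nuclear carry-over and more dividing macrophages cannot be told apart.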

How the results depend on the processing

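The leave-one-out list shifts, centred ratios, protein-coding pairs, scaled alignment-free counts for list spread and the lists without Rn7s1 and Rn7s2 or without Gm26917 were chosen after the data were seen. Of the alternatives run on the main results, 247 gave the same outcome, 22 moved a count or value, 5 lost the call and 1 reversed; of those on single lists, 404 gave the same outcome, 33 lost the call and 19 reversed. The causes were not tested unless stated. With only members of mean TPM of 1 or more, which leaves fewer genes, log2 differences fell to 1.61 (fast NF-κB minus late), 1.06, 6.22 and 5.24 (macrophage minus T and NK, B-lineage and megakaryocyte), below the threshold, and exported minus nuclear RNAs turned to -2.57; without Rn7s1 and Rn7s2 the last was 4.07, and with protein-coding transcripts only it has no value. The coefficient of variation ranged from 10% to 19.2% with each replicate left out. On alignment-free TPM, not scaled between libraries, 8 lists varied more and 6 less than matched lists, and ratios reversed to 0.72 (immediate early), 0.75 (fast NF-κB), 0.74 (late), 0.94 (pattern receptors), 0.83 (chemokines), 0.92 (antigen presentation), 0.90 (heat shock), 0.87 (macrophage) and 0.85 (NF-κB, IRF, STAT and AP-1 factors); the ribosomal protein ratio ranged from 0.82 to 2.28 with a replicate left out. Lists higher in replicate 1 numbered 1 with the length and GC trend removed and 4 to 5 with a replicate left out, and lists lower in replicate 2 numbered 4 to 13. With that trend removed, oxidative phosphorylation in replicate 2 moved to -0.02. Shifts with a replicate left out are deviations from a mean of 2 libraries, so their scale differs from that of the main shifts. With a replicate left out, replicate 1 shifts ranged from -0.32 to 0.08 (interleukins), -0.13 to 0.04 (antigen presentation), -0.03 to 0.39 (mitochondrially encoded), -0.02 to 0.14 (ribosomal proteins), -0.85 to 0.01 (nuclear-retained) and -0.05 to 0.02 (NF-κB, IRF, STAT and AP-1 factors), fast NF-κB in replicate 2 from -0.30 to -0.00, and cell-cycle genes in replicate 3 from -0.45 to 0.01. At a mean count of 20 or more, which tests more genes, genes differing over 2-fold numbered 472 up and 34 down in replicate 2 against 1, 99 and 64 in replicate 3 against 1, and 166 and 594 in replicate 3 against 2; the first was 217 by the alignment-free tables and 83 over protein-coding genes, which left 9 lower in replicate 3 than 1. Between the quantifications, 195 genes were higher and 6312 lower by the alignment-free method at a mean TPM of 1 or more, 142 lower over 200 nt, and 55 and 62 with centred ratios. The 6312 include genes lowered by the smaller TPM share of protein-coding genes in the alignment-free tables. Retained-intron shares called 4 lists with the alignment-free tables. At 2, 2 and 3 counts, Ifnb1 did not exceed the 3 counts that a count of 0 allows, so differences in its level were not detectable at this depth.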

Other observations

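Counts assigned to annotated ribosomal RNA differed between the libraries. Genes annotated as ribosomal RNA had 2158, 5473 and 30001 alignment-based counts in replicates 1 to 3, or 0.004, 0.013 and 0.078% of counts, and 0.021, 0.050 and 0.187% by the alignment-free tables. Most lay on CT010467.1, and mt-Rnr1 and mt-Rnr2 were also highest in replicate 3, the library in which mitochondrially encoded mRNAs were lowest. Gm42418, opposite CT010467.1, had 7237, 19402 and 4555 counts, and Gm26917, which ends just before it, had 8682, 47513 and 8149. Both were highest in replicate 2. Since strandedness is not given, which library held the most ribosomal RNA is uncertain. Of 12744 tested genes, 39.4% were highest in replicate 2, 34.0% in replicate 3 and 26.6% in replicate 1.

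Protein-coding genes were also ranked by how much their retained-intron share rose in replicate 2. In 5 groups of like size, ordered from the smallest change to the largest, the median log2 CPM deviation in replicate 2 was -0.006, -0.020, -0.027, -0.015 and 0.029.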
